A study of Caenorhabditis elegans with 4 samples.

How the data were processed

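Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was done on adult Caenorhabditis elegans hermaphrodites of the fem-2(b245) strain at 20 °C. The antibody was an affinity-purified rabbit polyclonal against ZHP-3. Per the labels' protocols, frozen worms were ground, fixed with 1% formaldehyde for 10 minutes and sonicated, and 5 µg of antibody was used per precipitation. The 4 libraries were 2 ChIP libraries and 2 libraries of input DNA, numbered 1 and 2 in each group. The labels do not say whether the replicates came from separate worm cultures, so any agreement between them may be technical.

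Each peak's start, end and score were read from 3 peak lists. The score is the authors' own value for each peak, as their peak caller wrote it, and it was used here to rank, describe or filter peaks within a list and, between the replicate lists, which share a caller name and a lowest score, to set overlapping peaks side by side. Per the file headers, the coordinates are on WormBase WS220. The submitters' processing notes name BWA and the ce10 build. The source column of the files names MACS, with no version, for the list of each ChIP replicate, and MACS v2 for a list of the whole series. That series-level list is called the combined list below, without any claim on how its peaks were made: whether reads or calls of the replicates were pooled, which control was used and which threshold was set are not given in the sources used here. The lowest score was 50.03 in both replicate lists and 1.31 in the combined list, and the scale of each score is not named in the files. In the replicate lists many peaks share a score of exactly 3100, namely 109 peaks in replicate 1 and 212 in replicate 2, so the order among the strongest peaks is partly lost. Scores of the combined list and of the replicate lists were never compared in value, and only ranks within each list were set side by side. Peak lists hold no read counts, so sequencing depth is unknown, and the input libraries were not analysed here.

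All steps were run in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9. Peaks of different lists were called overlapping when they shared at least 1 bp. The overlap count of the replicate lists was checked against bedtools 2.31.1 and was identical. Chance overlap was taken from 1000 circular shifts of one list within each chromosome, which keep the number, width and spacing of its peaks. The one-sided permutation p can then not go below 0.001. For the reciprocal and midpoint overlap alternatives 200 shifts were drawn, with a smallest p of 0.00498. Score agreement was Spearman's rho, and Pearson's r of log10 scores, over pairs of peaks that overlap one to one, with 100000 permutations. Peaks are not independent replicates, so these p-values describe the lists. Chromosome lengths were taken as the largest peak end over the 3 lists. The X chromosome was compared with the 5 autosomes by an exact permutation over the 6 chromosomes, whose smallest possible p is 0.167. Arms were the outer parts of each chromosome and the centre its middle part, all 3 parts of equal length, and the mean log2 ratio of their peak densities was tested with an exact two-sided sign-flip test over 6 chromosomes (64 flips, smallest p 0.03125). The interval of that mean comes from inverting the same test. Shares are given with Wilson 95% intervals, which cover counting error only and treat peaks as independent. The 3 peaks on mitochondrial DNA, all in the combined list, were left out of every comparison.

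On simulated lists with the real sizes and widths, a planted overlap of 60% gave 63.0% against 63.1% expected with chance overlap added. For the arm comparison, a planted 1.5-fold excess on the arms over 11840 peaks was recovered as a log2 ratio of 0.58. It passed the threshold of 0.05 in 40 of 40 runs, against 2 of 40 runs with no excess. These simulated peaks were single points without clustering, with the same planted ratio on every chromosome. The pass rates therefore describe an easier setting than the real list.

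Groups, tests, the rule for named peaks and the first set of alternatives were fixed before the data were examined. The rule names the 10 highest-scored combined peaks that overlap a peak in both replicate lists, the highest such peak of each chromosome, the 3 widest such peaks, and the highest-scored peak of each replicate list that lacks an overlap in the other. Those alternatives were stricter score limits (the upper 50% and the upper 25% of each list), a reciprocal overlap of 50%, midpoint overlap, random placement in place of shifts, lists of the same length, covered bases in place of peak numbers, published recombination domains in place of equal parts, autosomes alone, and each replicate list alone. Alternatives added after the data were seen left out peaks inside dense runs, left out pairs with a score of 3100 or more, or took 1 Mb windows as units for the X chromosome. A position of peaks relative to genes and a test of gene lists (meiotic, germline, ribosomal, somatic tissue markers and others) had been planned for an annotation of the build of the files. No WS220 annotation was used here, and coordinates of different builds were not mixed, so peaks are given by position and not by gene. Dense runs of peaks were defined after the data were seen, as at least 10 combined peaks with gaps of at most 1500 bp, and were tested against 1000 reshufflings of the gaps and widths within each chromosome.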

Results

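ZHP-3 is a RING-finger protein required for meiotic crossovers in C. elegans, and fem-2 is a sex-determination gene whose loss feminises the germline. ZHP-3 ChIP-seq was done on germline-containing young adults of the fem-2(b245) strain with 2 ChIP libraries, each with an input library of the same number. The lists analysed held 5981 peaks of ChIP replicate 1, 7001 peaks of ChIP replicate 2 and 11843 peaks of a combined list for the series, of which 11840 lie on the 6 nuclear chromosomes. The mean over the replicate lists was 6491 ± 721 peaks (SD, n = 2). Peaks were narrow, with a median width of 452 bp in replicate 1, 441 bp in replicate 2 and 324 bp in the combined list. They covered 3.47% of the chromosomes in replicate 1, 4.04% in replicate 2 and 5.52% in the combined list. The lists hold no read counts, so the depth behind each peak is unknown.

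The first question was whether the replicates gave peaks at the same sites. Of the 5981 peaks of replicate 1, 5223 overlapped a peak of replicate 2, which is 87.3% (Wilson 95% interval 86.5 to 88.1). In the other direction 5229 of 7001 peaks overlapped, or 74.7% (73.7 to 75.7). Circular shifts within chromosomes gave 7.82% on average and at most 9.71% for replicate 1 peaks, so the observed overlap was 11.2-fold above chance (one-sided permutation p = 0.001, the smallest 1000 shifts can give). Such overlap does not tell ZHP-3 binding from other sources of peaks shared by both libraries, since the input was not analysed here. Overlap followed the score within each list. Among the upper 25% of replicate 1 peaks by score 98.8% were found in replicate 2, against 66.7% among the lowest 25%. For replicate 2 these shares were 96.3% and 41.9%. Replicate 1 peaks with a partner had a median score of 232 and a median width of 471 bp, whereas the 758 without one had medians of 81.6 and 324 bp.

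Peak scores also went together between the replicates. Over 4873 pairs of peaks that overlapped one to one, the scores had a Spearman's rho of 0.79 and a Pearson's r of 0.81 on the log10 scale (permutation p = 1e-05 for each, the smallest 100000 permutations can give). This relation is across peaks, which are not independent replicates. Replicate 2 gave the higher score in 73.0% of the pairs, with a median ratio of 1.39 to replicate 1. Depth is unknown and the scale of the score is not named, so this difference cannot be read as stronger binding. In 198 pairs a score was at or above 3100, the value at which many peaks are tied.

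A few high-scored peaks were listed in a single replicate. The highest-scored replicate 1 peak with no overlap in replicate 2 lay on chromosome V from 3978025 to 3981530 (WS220), with a score of 3100 and a width of 3506 bp. The highest such peak of replicate 2 lay on chromosome I from 10945915 to 10953110, 7196 bp wide, also at 3100. Both regions held peaks in the combined list, 3 in the first with a top score of 35.5 and 6 in the second with a top score of 30.7. Among the upper 25% of each list by score, 18 of 1495 peaks of replicate 1 and 64 of 1750 of replicate 2 lacked a partner.

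The 10 combined peaks with the highest combined score were taken among those overlapping a peak in both replicate lists. Of these, 4 lay on chromosome IV, 3 on I, 2 on III and 1 on X, with none on II or V. Their combined scores ran from 158.69 to 161.45 and their widths from 800 to 3185 bp. The highest score, 161.45, belonged to a peak on chromosome IV from 3313009 to 3313853, and others on IV lay from 3725538 to 3726424, from 9066034 to 9069218 and from 9196063 to 9197707. On chromosome I they lay from 3930987 to 3932210, from 7894709 to 7895609 and from 10421011 to 10422528. On chromosome III they lay from 10807078 to 10808581 and from 13643181 to 13643980, and on X from 11605159 to 11606502. The highest such peak of chromosome II, from 14561349 to 14562054, scored 156.02 and ranked 21 in the combined list. That of chromosome V, from 6070903 to 6072970, scored 154.29 and ranked 26. In the replicate lists the order differed. The peak overlapping the highest-scored one, on IV at 3313009, ranked 197 by score in replicate 1 and 274 in replicate 2. The peak overlapping the one on X at 11605159 scored 3100 in both.

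The 3 widest combined peaks found in both replicate lists ranked 2812, 19 and 364 by combined score, in the order given here. One of 11130 bp lay near the right end of chromosome I, from 15060226 to 15071355. The ribosomal DNA array is known to sit at that end of the chromosome, and reads from such repeats cannot be assigned to single copies. It ran from 15060222 to 15071353 in replicate 1 and from 15060212 to 15071349 in replicate 2, and its score was 771 in replicate 1 and 3100 in replicate 2. The other 2 lay on X from 16929183 to 16940188, with a combined score of 156.61, and on V from 7915720 to 7925021, with 110.18. The region on X was split into 4 peaks in replicate 1 and 2 in replicate 2, whereas that on V was 1 peak in each. The highest score in both regions was 3100 in each replicate.

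The combined list was then compared with the replicate lists to see how far it rests on each. Of its 11840 nuclear peaks, 5022 overlapped a peak in both replicates, or 42.4% (Wilson 95% interval 41.5 to 43.3). A further 1677 overlapped a peak of replicate 2 alone and 733 of replicate 1 alone, and 4408, or 37.2% (36.4 to 38.1), overlapped none. Conversely, 99.6% of replicate 1 peaks and 98.7% of replicate 2 peaks were in the combined list. Peaks found in both replicates had a median score of 38.1 (quartiles 23.2 and 65.2) and a median width of 495 bp. Peaks found in neither had a median score of 5.21 (3.71 and 7.41) and a median width of 212 bp.

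**Figure D1:**
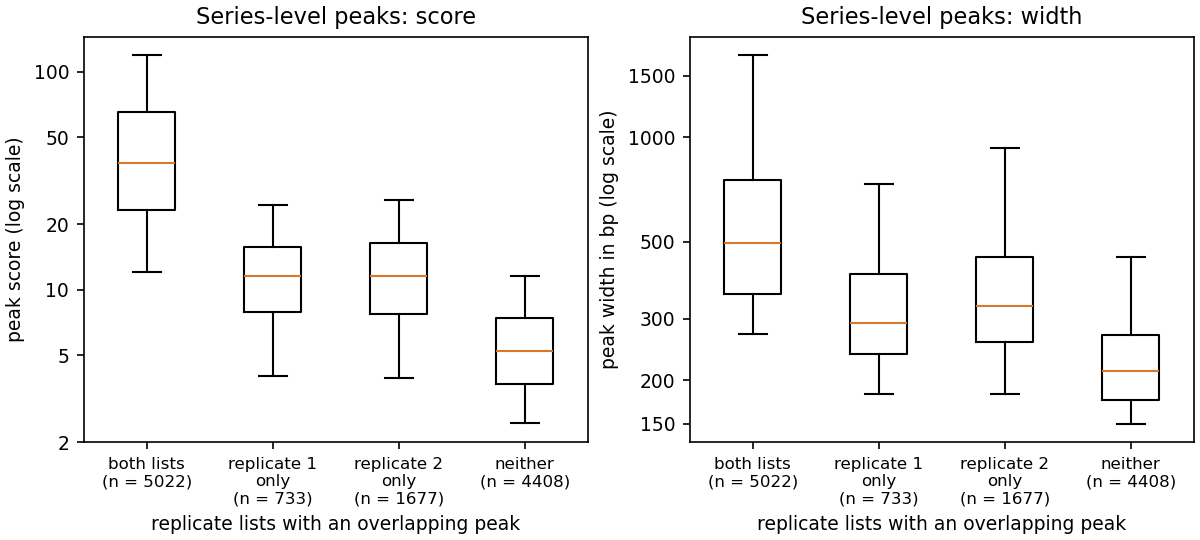
Score (left) and width in bp (right) of the combined, series-level peaks on log axes, by which replicate lists hold an overlapping peak. Boxes show median and quartiles and whiskers the 5th and 95th percentiles. The 5022 peaks found in both lists have a median score of 38.1, and the 4408 found in neither a median of 5.21.

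Chromosomes III and I held the most peaks per Mb in both replicate lists and in the combined list. Chromosome III was densest, with 150.2 peaks per Mb in the combined list and 83.1 ± 9.5 (SD, n = 2) in the replicate lists, followed by chromosome I with 137 and 75.3 ± 5.3. Chromosomes II and IV had 118 and 115 peaks per Mb in the combined list. Chromosome V had 102 and X had 98.1, with replicate means of 54.4 ± 5.6 and 54.5 ± 9.9. X was the lowest chromosome in the combined list and in replicate 1, with 47.5 peaks per Mb, but in replicate 2 it had 61.6 and V, with 58.4, was lower. Chromosome III was 1.53-fold denser than X in the combined list, 1.61-fold in replicate 1 and 1.46-fold in replicate 2.

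**Figure D2:**
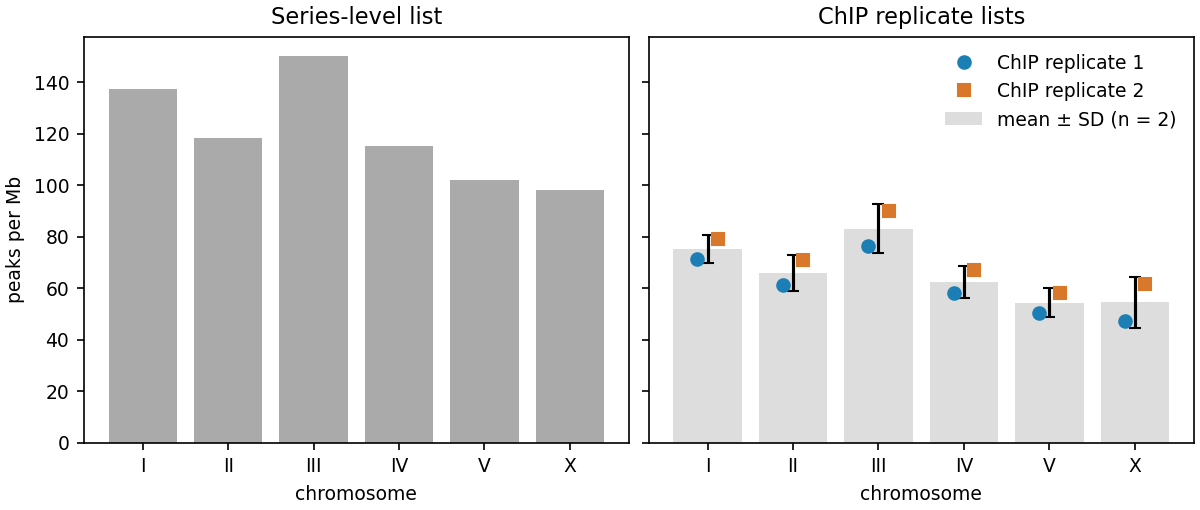
Peaks per Mb on each nuclear chromosome for the combined list (left) and for the ChIP replicate lists (right, points for each replicate, bars for mean ± SD, n = 2). Chromosome III is highest in every list, and replicate 2 lies above replicate 1 on each chromosome.

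The X chromosome is known to be poor in genes expressed in the worm germline, so its density was set against the autosomes. It held 98.1 peaks per Mb against 122 on the autosomes in the combined list, a ratio of 0.80. The ratio was 0.76 in replicate 1 and 0.86 in replicate 2 (mean 0.81 ± 0.07, SD, n = 2). X took 14.7% of the combined peaks (Wilson 95% interval 14.1 to 15.3) and 17.7% of the chromosome length. With whole chromosomes as the units, the deviation of X from the others was not singular: the exact permutation p over 6 chromosomes was 0.333 in the combined list, since chromosome III departed from the rest by more, and this design cannot go below 0.167. Among the upper 25% of each replicate list by score the ratio was 0.57 in replicate 1 and 0.64 in replicate 2, while it was 0.80 in the upper 25% of the combined list. Combined peaks shared with replicate 2 alone had a ratio of 1.10, and those shared with replicate 1 alone a ratio of 0.51.

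Crossovers in C. elegans fall mostly on the chromosome arms, so peak density was compared between arms and centre. No difference in the density of called peaks was detected. The combined list had 119.5 peaks per Mb on the arms and 122 in the centre, and the log2 ratio of arms to centre was -0.02 ± 0.12 (SD over n = 6 chromosomes, exact sign-flip p = 0.688, two-sided). The interval of that mean reached from -0.12 to 0.13, so a 1.5-fold difference (log2 0.58) in the number of called peaks lies outside it. The called peaks were narrow and read coverage was not analysed. Enrichment of ZHP-3 spread over whole arms was therefore not tested. Replicate 1 gave -0.06 ± 0.08 (exact p = 0.156) and replicate 2 gave -0.11 ± 0.12 (exact p = 0.0938). In each replicate list X alone had more peaks per Mb on its arms, with log2 ratios of 0.08 and 0.09, and in the combined list chromosomes I (0.12) and X (0.13) did. Peaks found in both replicates had a ratio of -0.11 (exact p = 0.0938) and peaks found in neither 0.12 (exact p = 0.188).

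**Figure D3:**
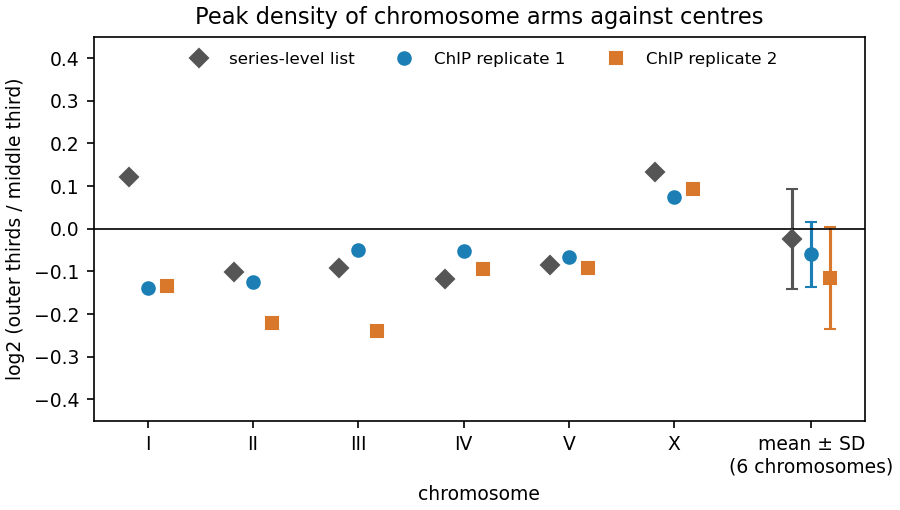
Log2 ratio of peaks per Mb in the outer parts of each chromosome to the middle part, for the combined, series-level list and both ChIP replicates, with the mean ± SD over 6 chromosomes at the right. The means are -0.02, -0.06 and -0.11, and X lies above 0 in all 3 lists.

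Density was also counted in smaller windows along the chromosomes. Over 197 windows of 500 kb, the median was 29 peaks in replicate 1 and 33 in replicate 2. The window from 3.0 to 3.5 Mb of chromosome V was the emptiest in all 3 lists, with 8 peaks in replicate 1, 10 in replicate 2 and 21 in the combined list. The window from 6.0 to 6.5 Mb of the same chromosome held 54 peaks in replicate 1, its highest, and 76 in replicate 2. The window from 7.0 to 7.5 Mb of chromosome III was the highest of replicate 2, with 84 peaks, and of the combined list, with 128, and held 48 in replicate 1.

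**Figure D4:**
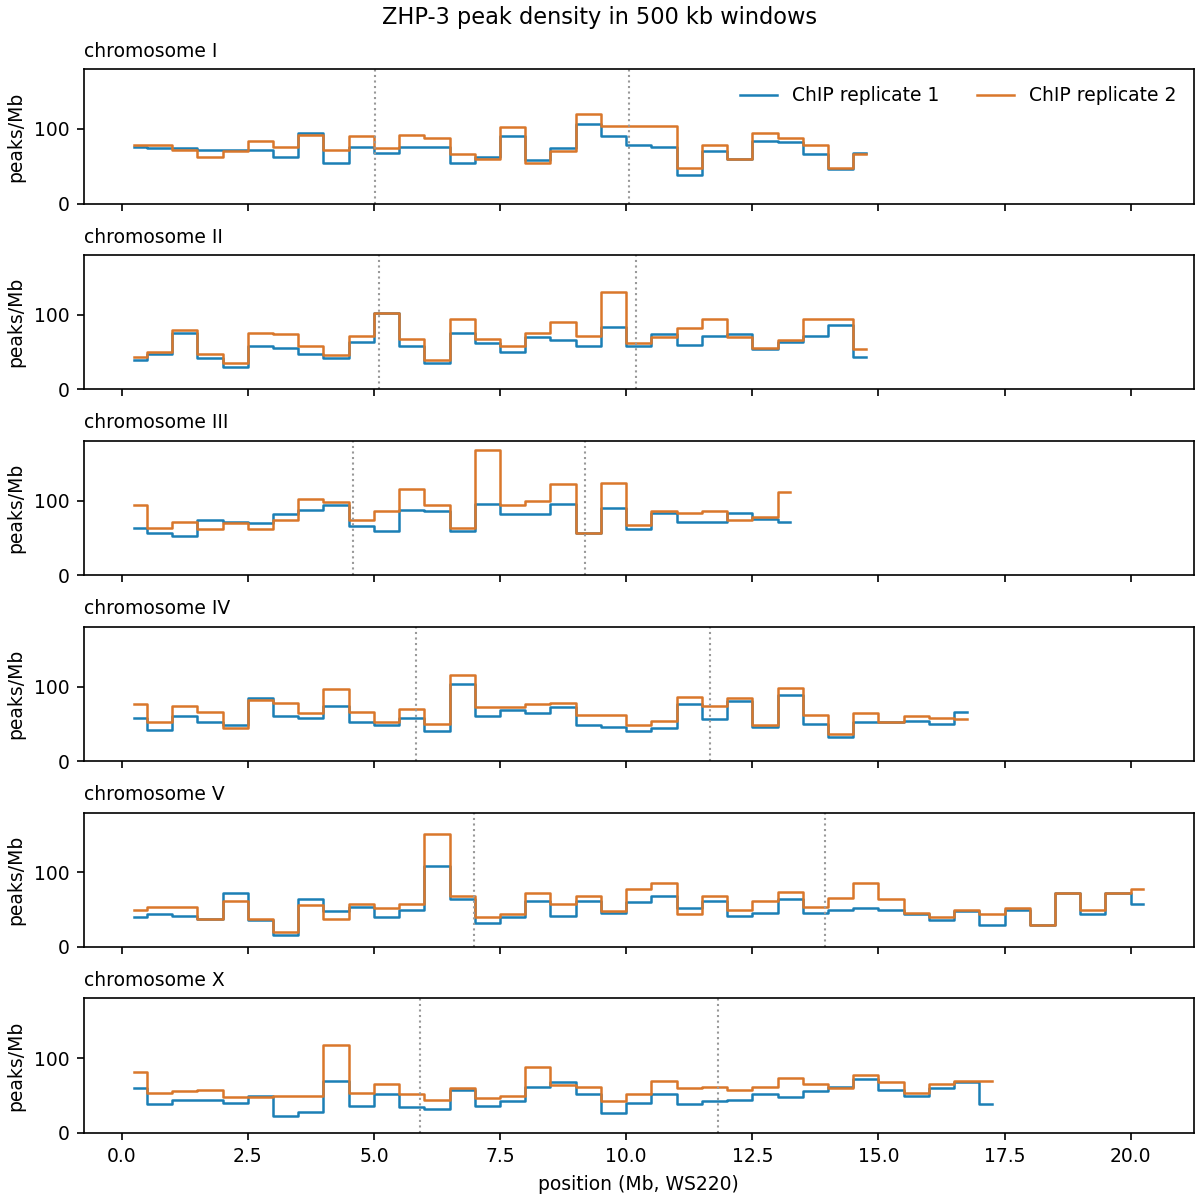
Peaks per Mb in windows of 500 kb along each chromosome (position in Mb, WS220) for both ChIP replicates, with dotted lines between the outer and middle parts. The windows of chromosome III from 7.0 Mb and of chromosome V from 6.0 Mb stand highest in replicate 2, at 168 and 152 peaks per Mb (84 and 76 peaks).

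Part of this local density came from runs of closely spaced peaks, a feature picked after the data were seen. The combined list held 22 runs of at least 10 peaks with gaps of at most 1500 bp, spanning 6.13 to 36.0 kb and holding 308 peaks, or 2.60% of the list. The run with the most peaks lay on chromosome III from 7405446 to 7441473, with 42 combined peaks over 36.0 kb, none scoring above 12.7. Replicate 1 had 4 peaks in it and replicate 2 had 28. The next lay on chromosome V from 6070903 to 6096239 and held 26 combined peaks, with 18 peaks of replicate 1 and 32 of replicate 2. It begins with the highest-scored combined peak of that chromosome found in both replicate lists. A run on chromosome I from 4341528 to 4357132 held 21 combined peaks, 0 peaks of replicate 1 and 2 of replicate 2.

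**Figure D5:**
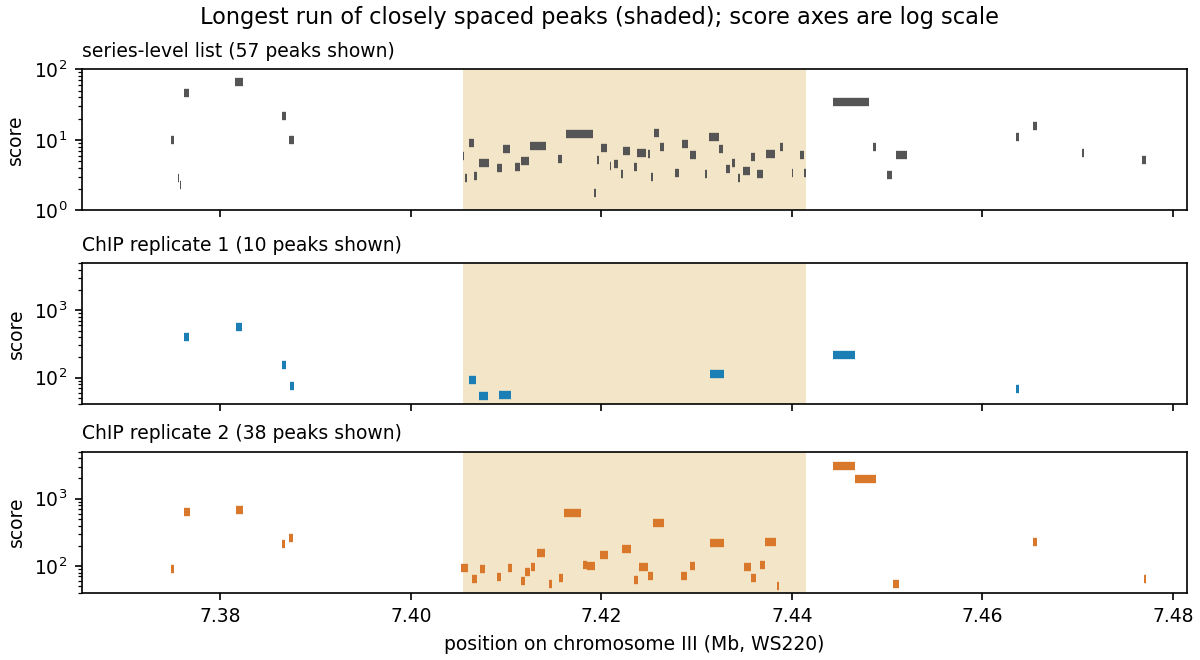
Peaks of the 3 lists around the run on chromosome III from 7405446 to 7441473 (shaded), each drawn from its start to its end at its score on a log axis; the combined, series-level list is at the top and score scales differ between lists. Inside the run replicate 1 has 4 peaks, replicate 2 has 28 and the combined list has 42.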

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

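Replicate overlap kept its direction and its side of the threshold under all 7 alternatives, with 82.0% to 87.4% of replicate 1 peaks shared, and score agreement did so under all 5, with rho from 0.77 to 0.81. One alternative of each was chosen after the data were seen: outside the dense runs (87.4%) and without scores of 3100 or more (rho 0.77). The share of combined peaks found in both replicates moved beyond its counting interval only when 50% of each peak had to be shared (38.3%, against 42.4%). The other 3 alternatives for that share stayed within the interval. One of them took the upper 50% of each list by score (42.2%). It limited the replicate lists as well, so it does not test the score limit of the combined list alone. The X to autosome ratio stayed below 1 in all 7 alternatives (0.75 to 0.86). Among them, 0.76 without replicate 2 and 0.86 without replicate 1 are the values of the remaining replicate list, already given above. With chromosomes as the units no p can go below 0.167; the ratio passed the threshold in one alternative, chosen after the data were seen, in which 1 Mb windows were the units (ratio 0.80, permutation p = 6e-04). Neighbouring windows of one chromosome are not independent, which that test ignores. The mean log2 ratio of arms to centre passed the threshold in none of the alternatives over 6 chromosomes; over the 5 autosomes alone it was -0.06, where the test cannot reach the threshold and says nothing about stability. It was -0.11 without replicate 1 and -0.06 without replicate 2, again the values of the remaining replicate list. With published recombination domains it was -0.06 (exact p = 0.25). Outside the dense runs, an alternative chosen after the data were seen, its sign turned to 0.0037 (exact p = 0.938). The 10 highest-scored combined peaks were picked among those overlapping a peak in both replicates. All 10 were also found in both under the reciprocal 50% and midpoint rules. Runs numbered 17 with gaps of at most 1000 bp and 8 with gaps of at most 3000 bp and at least 15 peaks. No paired analysis was possible because the input libraries, which share the replicate numbers, were not analysed here. Leaving out a replicate leaves no value for the overlap and score agreement. Positions in genes and gene lists, with their other settings, were not run, because no annotation of the same build was used here. Depth is unknown, so a site missing from a list cannot be told from one below the caller's limit.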

Other observations

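The tests of the runs, of the chromosome ends and of the score limit were chosen after the result was seen. The tests of flanking peaks and of the X to autosome gap were written before their own results were seen but after the data had been examined, the latter with runs defined from the data and with intervals added afterwards.

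Peaks sat at the very start of most chromosomes. Replicate 2 had a peak within 1000 bp of the left end of 6 of 6 chromosomes, replicate 1 of 5 (all but III) and the combined list of 4 (I, II, V and X). Circular shifts gave 0.396, 0.316 and 0.645 ends on average, and as many ends as observed with permutation p = 0.001, 0.001 and 0.002, where 0.001 is the smallest 1000 shifts can give. The scores of these end peaks ran from 14.2 to 35.1 in the combined list, from 53.0 to 231 in replicate 1 and from 299 to 1716 in replicate 2. Within their own lists they stood at percentiles 1.5 (II) to 55.3 (V) in replicate 1 and 57.8 (III) to 92.9 (I) in replicate 2. Only chance placement was tested, so where these peaks come from is open. Right ends could not be tested, because the chromosome lengths were themselves taken from the last peaks. The mitochondrial genome carried peaks in the combined list alone, at 102 to 10478, 10722 to 11851 and 11903 to 13269, with scores between 7.83 and 17.1; together they span 12874 bp.

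Of the combined list, 4408 peaks or 37.2% have no partner in either replicate list. A lower score limit in the combined list stays open as a candidate explanation: 99.95% of these peaks scored below the lower quartile (23.2) of peaks found in both replicates, but so did 92.0% of the 2410 peaks found in a single replicate list, so the share does not decide. Another candidate, that they are flanks of regions called in a replicate, is argued against for most of them: 29.7% (Wilson 95% interval 28.3 to 31.04) lay within 1000 bp of a replicate peak, where at least 50% had been required. That share is still above the 12.8% given by circular shifts, so flanks may account for a part. No biological explanation was tested, since the design has no second condition.

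The X to autosome ratio was higher in replicate 2 (0.86) than in replicate 1 (0.76), a gap of 0.097 with a 95% interval of 0.032 to 0.161 from redrawing 1 Mb windows. Each ratio rests on 1 library, so that interval covers spread along the genome and not between libraries. Neighbouring windows are also not independent. Outside the dense runs 111% of the gap was kept (101 to 139). This was a weak test of the runs as the source. Of the 22 runs 2 lay on X and 20 on autosomes, so leaving them out could hardly lower the gap. The 2 runs on X held 10 and 7 peaks of replicate 1 and 11 and 9 of replicate 2, and so added few peaks to it. The longer list of replicate 2 stays open: with both lists limited to the same number of top-scored peaks 85.3% of the gap was kept, but the interval, 52.7 to 120, reaches below the 80% that would have excluded it. No biological explanation was tested, since both libraries carry the same labels.

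The 22 dense runs were more than reshuffled gaps gave, which was 0.807 runs on average and at most 5 (permutation p = 0.001, the smallest possible). Reshuffling evens out density along each chromosome, so it does not tell the runs from wider differences in density. The runs held 196 peaks of replicate 2 and 118 of replicate 1, a ratio of 1.66 (95% interval 1.21 to 2.27 over runs). That interval lies above the ratio of list lengths, 1.17. Without the run on chromosome III at 7405446 the ratio was 1.47 (1.10 to 1.87), an interval that includes 1.17. The result thus hangs on 1 run, and the list lengths are not excluded as the source of the ratio. Their combined peaks had a median score of 6.31, against 12.9 elsewhere. Extra copies of these regions, or cloned DNA in the libraries, is a candidate explanation for long runs of weak peaks such as the one of 36.0 kb. It cannot be told apart from broad binding here, because the input coverage that would decide was not analysed.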
